A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

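The series compared wild type *Saccharomyces cerevisiae* (budding yeast) with a ppt1 mutant, labelled as a deletion of PPT1, the gene of a serine/threonine protein phosphatase that acts on Hsp90, at 5 times around a shift to lower osmolarity (hypo-osmotic shock). Each array was a 2-colour array hybridised with total RNA of 1 sample in channel 1 and a reference in channel 2, per the labels. There was 1 array for each strain and time: 0, 7, 16, 30 and 60 min in the wild type and 0, 7, 15, 30 and 60 min in the mutant. The 16 min and 15 min arrays were treated as 1 time point, written 15-16 min. Nothing in the labels says whether the 5 times of a strain came from 1 culture or from several, so p-values measure only the spread between these arrays, which may be technical.

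The deposited values were log ratios of the 2 channels, 1 per gene and array, and were taken as log2. The base, the platform, the dyes, the scanner, the background correction, the normalization and the way spots were combined are not given in the sources used here. A base of 10 would make the largest value a 115000-fold ratio, beyond the 65536 levels of a 16-bit scanner. A natural log was not excluded, and it would enlarge every log2 value by the same factor without changing a limma count or an adjusted p, but it would change the counts at a fixed 2-fold. The deposited arrays were close to centred, with medians from -0.08 to 0.01. The direction of the ratio was taken as sample over reference, which is likely but not stated. Its basis is that the labels call channel 2 the reference, and that genes known to be induced by high osmolarity were highest before the shift to low osmolarity. With the ratio turned, every direction would turn with it.

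The table held 5822 genes, each with a value on at least 8 of the 10 arrays and 4901 of them with a value on all 10 arrays. Missing values made up 1.81% of the table. Systematic names were matched to gene symbols through a RefSeq gene table of assembly R64, which named 5358 genes, and the other 464 kept their systematic name. No genome build was named for the arrays, so no coordinates are given. On the wild type 0 min array, 43.02% of values had 4 decimals, and the last of them was a 5 in all 2498. The other arrays had 0 such values.

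Each array was centred on its median. limma 3.58.1 in R 4.3.3 fitted the time point and the strain as additive terms to all 10 arrays, with 4 residual degrees of freedom and 5.8 prior degrees of freedom. Each later time was set against 0 min with the strains serving as the 2 replicates of a time, a moderated F test covered any change over time, and the strain term compared the 5 arrays of each strain matched by time. A second fit added an interaction, the strain difference after shock minus that at 0 min, with 3 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. A strain's own response had no replicates and was given as values. The number of arrays limits the precision of every value.

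The fits were tested on simulated arrays with the real missing values, 5822 genes of which 200 were changed, in 5 runs. Errors were drawn independently for each gene from the fit's own model of the spread. Links between genes and deviating arrays were not simulated, so the rates below hold only under that model. For the response at 7 min, 85.7% of 2-fold and 14.6% of 1.41-fold changes were recovered, with 5.82% of calls false. For the strain difference, 98.5% of 2-fold and 71% of 1.41-fold changes were recovered, with 5.37% of calls false. For the interaction, 93.9% of 4-fold, 22.1% of 2-fold and 1.19% of 1.41-fold changes were recovered, with 6.05% of calls false. With no change simulated, 0 genes were called. With lists of 25 simulated unlinked genes, camera called 20 of 20 shifted lists and 0 of 480 unshifted ones.

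Before the data were examined, 25 gene lists were fixed: PPT1 and its neighbours, cell wall integrity (Slt2-Rlm1) targets, the HOG pathway and glycerol synthesis, water and glycerol channels and transporters, the general stress response (Msn2/Msn4), Hsp90 with co-chaperones and Hsf1 targets, cytosolic ribosomal proteins, ribosome biogenesis, pheromone response, a-cell markers, alpha-cell markers, amino acid synthesis (Gcn4), auxotrophic marker genes, sulfate assimilation and methionine, phosphate starvation (Pho4), calcineurin (Crz1) targets, glycolysis and fermentation, ergosterol synthesis, the TCA cycle and respiration, histones, G1/S and G2/M cell cycle genes, the iron regulon (Aft1) and the proteasome, with 1 further list that is not reported here but stays in the adjustment. The name pattern for ribosomal proteins also took in RPP1, a subunit of RNase P. limma's camera tested the lists on the genes with all 10 values, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists and 6 contrasts. With a correlation estimated from the data, 0 of the 150 tests passed, and the lowest adjusted p was 0.0658. With that setting camera also draws on the few residual degrees of freedom of the fit. With the fixed correlation it draws on the number of genes instead. These settings therefore differ in more than the correlation. How much of the loss of calls is due to correlation between genes was not tested.

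Named genes followed a rule fixed at the same point: PPT1. For the response, the 12 highest and 12 lowest of the genes past the F test whose largest change had the same sign in both strains. For the strain difference, the 12 highest and 12 lowest of the genes that passed with the same sign in at least 4 of 5 matched pairs, or in all pairs measured. For the interaction, the 5 highest and 5 lowest by moderated t where none passed. For each list described, up to 4 members with the largest change. Alternatives covered centring, quantile normalization and scaling, missing values, robust moderation, array weights, model terms, the log base, and leaving out each array or time point. For the lists they also covered limma's fry, which asks whether a list's genes changed without setting them against the other genes. Added after the data were seen were each time set against the time before it, and lists of purine and one-carbon synthesis, pyrimidine synthesis, zinc-regulated genes and further Hsf1 targets. Intervals of list medians came from 10000 bootstrap draws over the genes of a list, at 95%. They do not measure the spread between arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. All 10 arrays and all 5822 genes were used.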

Results

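Gene expression was measured in wild type budding yeast and in a strain labelled as a PPT1 deletion, before a shift to lower osmolarity and at 4 later times, on 10 2-colour arrays against a reference. The design asked how transcript levels change after the shift and whether they differ in the mutant. No unshifted culture was followed over time, so changes after the shift cannot be told apart from changes with time or handling alone. Each strain and time had 1 array, so single values have no replicate error, and the errors given are standard errors (SE) of the fit over all 10 arrays. The arrays held between 5440 and 5807 genes with a value. Each pair of arrays correlated positively across genes, with r of at least 0.366, and genes are not independent replicates. Values are log2 ratios, likely of sample over reference, and directions below rest on that reading.

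PPT1 was examined first, because a deleted gene checks the labels. It was not lower on the arrays labelled ppt1. The centred log2 ratio of PPT1 at 0, 7, 16, 30 and 60 min was -0.50, -0.21, 0.07, -0.16 and -0.44 in the wild type. On the arrays labelled ppt1, at 0, 7, 15, 30 and 60 min, it was 0.10, 0.40, 0.07, -0.32 and -0.55. The fitted difference for PPT1, labelled ppt1 minus wild type, was 0.19 ± 0.13 (SE, 5 matched pairs; limma adjusted p = 0.417). PPT1 was higher in 3 pairs and lower in 2. Its neighbours on the chromosome, ASN2 (-0.05 ± 0.08) and YGR122W (-0.02 ± 0.18), did not pass either, and the list of the 3 genes passed no test. Which part of PPT1 the spot reads is not given in the sources used here, so PPT1 neither bears out the label nor settles the direction of the ratio. The mutant arrays are therefore called the arrays labelled ppt1.

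**Figure D1:**
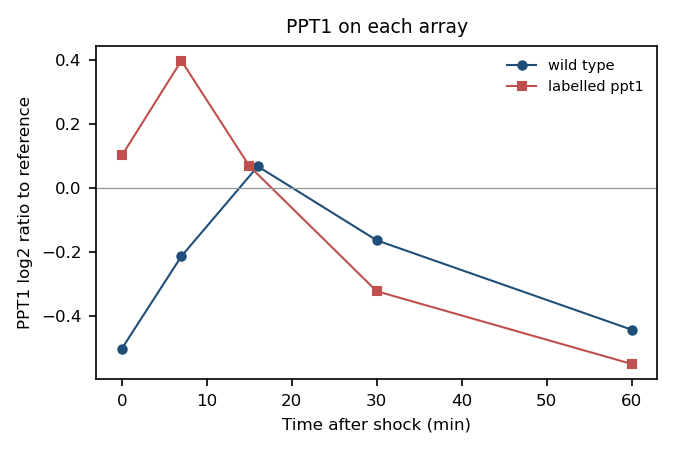
Centred log2 ratio of PPT1, likely sample over reference, against time after shock in min, with 1 point per array and lines joining the arrays of a strain. PPT1 lies higher on the array labelled ppt1 at 0 and 7 min, at 0.10 and 0.40, and lower at 30 and 60 min, at -0.32 and -0.55.

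At 7 min after the shift, over both strains, 7 of 15 genes of the HOG pathway and glycerol synthesis, 11 of 24 general stress genes, 8 of 25 cell wall integrity targets and 5 of 10 calcineurin targets fell, and 0 rose. The camera adjusted p of these lists lay between 2.4e-16 and 2.47e-05, and with an estimated correlation the adjusted p lay between 0.0658 and 0.0789. GPD1, the glycerol-3-phosphate dehydrogenase of glycerol synthesis, fell by 1.35 ± 0.17 on the log2 scale (limma adjusted p = 0.00334), and GPP2, the following phosphatase, fell by 0.97 ± 0.14 (adjusted p = 0.00512). CMK2, a calmodulin-dependent kinase induced through calcineurin, fell by 2.05 ± 0.14 (adjusted p = 0.000141), and NCW2, a cell wall protein gene, fell by 2.05 ± 0.13 (adjusted p = 0.000141). HRP1, an RNA-binding protein of mRNA 3' end processing, rose by 1.23 (adjusted p = 0.00143), and CAR1, arginase, rose by 1.22 (adjusted p = 0.00283).

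In limma's fit, 176 genes passed at 7 min, 26 higher and 150 lower than at 0 min. At 15-16 min 418 genes passed (91 higher, 327 lower), at 30 min 661 (207 higher, 454 lower) and at 60 min 719 (231 higher, 488 lower). The F test for any change over time passed 522 genes. The balance of higher and lower calls depended on scaling. Without centring it was 307 higher and 378 lower at 30 min and 387 higher and 388 lower at 60 min. With quantile normalization it was 17 and 36 at 7 min, 73 and 135 at 15-16 min, 206 and 231 at 30 min, and 203 and 248 at 60 min. Single arrays also moved the counts. Without the wild type 0 min array 44, 162, 344 and 342 genes passed at 7, 15-16, 30 and 60 min and 228 at any time, and without the 0 min array labelled ppt1 93, 178, 265 and 273 passed and 212 at any time. Without the wild type array of the time itself 47 passed at 7 min, 176 at 15-16 min, 379 at 30 min and 425 at 60 min. Without the array labelled ppt1 of the time itself 80 passed at 7 min, 296 at 30 min and 318 at 60 min, and without that of 60 min 344 passed at any time.

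The largest falls by 60 min were in RCK1, a protein kinase of the oxidative stress response (-4.92 ± 0.22, adjusted p = 1.64e-06), HSP12, a small membrane-associated stress protein (-4.21 ± 0.18, adjusted p = 1.64e-06), and ADE17 of purine synthesis (-4.18 ± 0.19, adjusted p = 1.64e-06). FMP48 (-3.92), PRM7 (-3.77), the unnamed YDL038C beside it (-3.71), YOR338W (-3.11), SPI1, a cell wall protein gene (-2.91), and PHO89, a sodium-phosphate transporter (-2.88), followed at the same time. YDL038C followed PRM7 closely over the arrays, so the 2 may read 1 transcript and need not be separate findings. The fall was largest at 15-16 min for OLE1, the fatty acid desaturase (-3.43), and ADE2 (-3.12), and at 30 min for SHM2, a serine hydroxymethyltransferase (-2.95). OLE1 stood at -1.87 ± 0.27 at 60 min. Among the genes that rose most, FRE1, a surface ferric and cupric reductase, was 1.78 ± 0.17 higher at 60 min (adjusted p = 0.000155), CAR1 1.58 higher at 60 min, and the chaperone gene SIS1 1.27 higher at 60 min. At 30 min ERG3, the sterol C-5 desaturase, was 1.75 higher, POL30, the replication clamp PCNA, 1.48, TMA10 1.39, the G1 cyclin gene CLN1 1.31, the iron oxidase gene FET3 1.30, TOS4 1.26 and YDR112W 1.25. HRP1 (1.64) and the S-phase cyclin gene CLB6 (1.36) were highest at 15-16 min. All 24 genes passed the test at the time given, with adjusted p from 1.64e-06 to 0.00195.

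Of the 25 cell wall integrity targets measured, 8 fell at 7 min and 18 at 60 min, and 0 rose at either time. Adjusted over the list alone, 8 and 22 fell. At 60 min NCW2 (-2.76 ± 0.13), SLT2, the MAP kinase of the pathway (-2.22 ± 0.20), SRL3 (-1.61 ± 0.14) and CHS1, a chitin synthase (-1.48 ± 0.17), had the largest changes. The list's median was -0.29 at 7 min and -0.94 at 60 min, with camera adjusted p = 2.47e-05 and 1.18e-14. With an estimated correlation the adjusted p = 0.0789 at 7 min and adjusted p = 0.0658 at 60 min. With quantile normalization the list did not pass at 7 min (adjusted p = 0.395) or at 15-16 min (adjusted p = 0.324).

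Of the 15 genes of the HOG pathway and glycerol synthesis, 7 fell at 7 min and 12 at 15-16 min and at 60 min, with 0 rising; adjusted over the list alone, 13, 14 and 14 fell, and 1 rose at 7 min and at 60 min. HSP12, GPP2 (-2.18 ± 0.14), GRE2 (-1.77 ± 0.13) and HOR7 (-1.42 ± 0.12) led at 60 min. GPD1 was at -0.67 ± 0.17 by then, against -1.35 ± 0.17 at 7 min. The list had camera adjusted p = 1.87e-08 at 7 min and 1.03e-08 at 60 min, and with an estimated correlation adjusted p = 0.0658 at both. Of the 24 Msn2/Msn4 general stress genes, 11 fell at 7 min and 14 at 60 min, with 0 rising; adjusted over the list alone, 18 and 16 fell. SOL4 (-1.61 ± 0.24), DDR2 (-1.46 ± 0.17), the glycogen synthase gene GSY2 (-1.32 ± 0.19) and the catalase gene CTT1 (-1.23 ± 0.23) had the largest changes at 7 min. This list had camera adjusted p = 2.4e-16 at 7 min and, with an estimated correlation, adjusted p = 0.0735. Of the 10 calcineurin targets, 5 fell at 7 min and 7 at 60 min, and 0 rose; adjusted over the list alone, 5 and 8 fell. CMK2, YPS1 (-1.53 ± 0.13), GYP7 (-1.42 ± 0.19) and PHO89 (-1.39 ± 0.21) changed most at 7 min, with camera adjusted p = 1.03e-08 and, with an estimated correlation, adjusted p = 0.0658. HSP12 and CTT1 stood in both the HOG and the general stress list, ENA1 in the HOG and the calcineurin list, STL1 in the HOG list and that of water and glycerol channels, GSC2 in the cell wall and the calcineurin list, PHO89 in the calcineurin and the phosphate list, HSP104, HSP26 and SSA4 in the general stress and the Hsp90 list, and MET17 in the sulfate list and that of auxotrophic markers.

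**Figure D2:**
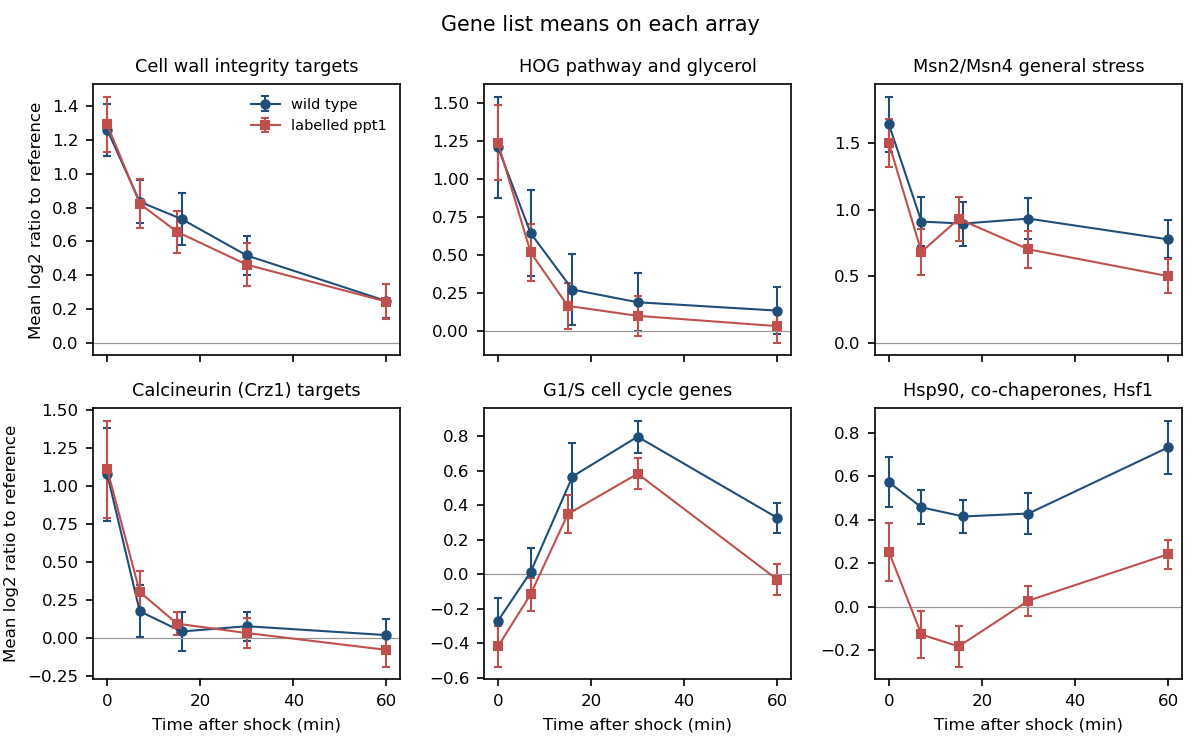
Mean centred log2 ratio, likely sample over reference, of 6 gene lists against time after shock in min, with 1 point per array and bars for the standard error across the genes of a list, which are not replicates. Cell wall integrity targets fall from 1.26 to 0.25 in the wild type and from 1.29 to 0.24 on the arrays labelled ppt1, while the Hsp90 list lies lower on the arrays labelled ppt1 at each time.

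Most cell cycle genes that passed rose. Of 7 G1/S genes, 6 rose at 15-16 min and 6 at 30 min, and adjusted over the list alone 6 and 7 rose. At 30 min POL30 (1.48 ± 0.14), CLN1 (1.31 ± 0.14), RNR1, the large subunit of ribonucleotide reductase (1.20 ± 0.14), and CLB6 (1.07 ± 0.17) led. The camera adjusted p = 1.03e-08 at 30 min and, with an estimated correlation, adjusted p = 0.0975. Of 6 G2/M genes, 3 rose at 7 min and 4 at 60 min; adjusted over the list alone, 4 and 4 rose. CLB2, a mitotic cyclin gene (1.23 ± 0.13), CDC5, the polo kinase gene (1.09 ± 0.14), BUD4 (0.96 ± 0.20) and SWI5 (0.47 ± 0.12) rose at 60 min, with camera adjusted p = 0.000286 and, with an estimated correlation, adjusted p = 0.139. At 30 min 2 G2/M genes rose and CLB1, another mitotic cyclin gene, fell (-0.91 ± 0.20, limma adjusted p = 0.0165), against 3 and 1 adjusted over the list alone, and the list did not pass at 15-16 min (camera adjusted p = 0.122) or 30 min (camera adjusted p = 0.209). Of 13 iron regulon genes, 5 rose at 30 min and 4 at 60 min, led at 60 min by FRE1, FET3 (1.11 ± 0.17) and FIT2 (0.75 ± 0.15); adjusted over the list alone, 6 rose at each of these times, and 1 and 2 fell. The camera adjusted p = 0.00472 at 60 min and, with an estimated correlation, adjusted p = 0.164. Of 8 histone genes, 2 rose at 60 min, HHF1 (0.48 ± 0.13) and HTA1 (0.45 ± 0.12), and 2 fell at 15-16 min; adjusted over the list alone, 3 rose and 2 fell. Camera called the list lower at 15-16 min (adjusted p = 0.00977) and higher at 60 min (adjusted p = 0.00545), and with an estimated correlation the adjusted p = 0.43 and adjusted p = 0.409.

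At 60 min 11 of 27 amino acid synthesis genes fell, among them ARG1 (-1.79 ± 0.27) and ARG3 (-1.64 ± 0.18), and 10 of 18 sulfate and methionine genes, among them MET17 (-2.75 ± 0.44) and MET6 (-1.97 ± 0.23), with 0 rising in either list. Adjusted over the list alone, 13 and 12 fell, and 1 sulfate gene rose. Their camera adjusted p = 0.000497 and 0.00117, and with an estimated correlation adjusted p = 0.133 and adjusted p = 0.392. Of 10 pheromone response genes 7 fell, among them KAR4 (-1.16 ± 0.15) and FIG1 (-1.06 ± 0.16), as many as adjusted over the list alone, with camera adjusted p = 8.71e-05 and, with an estimated correlation, adjusted p = 0.325. Of 12 phosphate starvation genes 3 fell, PHO89, PHO84 (-0.75 ± 0.15) and PHM6 (-0.69 ± 0.14), and 5 adjusted over the list alone (camera adjusted p = 0.001; with an estimated correlation adjusted p = 0.291). Of 6 auxotrophic marker genes 4 fell, ADE2, MET17, LEU2 (-2.16 ± 0.37) and HIS3 (-0.74 ± 0.16), and 5 adjusted over the list alone (camera adjusted p = 0.00579; with an estimated correlation adjusted p = 0.186). The 136 ribosomal protein genes had a median of 0.19 at 60 min and camera adjusted p = 8.18e-07, but only 3 rose, RPL4A (0.59 ± 0.13), RPL41A (0.57 ± 0.13) and RPS14B (0.50 ± 0.14), and 0 adjusted over the list alone; with an estimated correlation the adjusted p = 0.504.

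In several lists few members passed over all genes. Of the 30 ribosome biogenesis genes 1 rose at 7 min, RPA190, a subunit of RNA polymerase I (0.67 ± 0.13), where camera called the list higher (adjusted p = 0.00406; with an estimated correlation adjusted p = 0.477), and 1 fell at 60 min, NSR1 (-1.20 ± 0.22), the same counts as adjusted over the list alone. Of the 26 TCA cycle and respiration genes 0 passed at 7 min and 5 fell adjusted over the list alone, with camera adjusted p = 0.000101 and, with an estimated correlation, adjusted p = 0.32. At 15-16 min 1 of them fell, while 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.1e-05, and 0.316 with an estimated correlation). Of 16 glycolysis and fermentation genes 6 fell at 30 min, among them TDH1 (-1.15 ± 0.14), and HXK2 rose (0.85 ± 0.17), the same counts as adjusted over the list alone (camera adjusted p = 0.021; with an estimated correlation adjusted p = 0.223). Of 20 ergosterol genes 2 rose at 30 min, ERG3 and ERG5 (1.01 ± 0.13), and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.123). Of 5 water and glycerol channel genes 1 fell at 60 min, the aquaporin gene AQY1 (-0.63 ± 0.13), while 1 fell and 1 rose adjusted over the list alone, and the list did not pass (adjusted p = 0.674). Of 31 proteasome genes 0 passed at each time, also adjusted over the list alone, and camera called the list higher at 7 min (adjusted p = 0.0316; with an estimated correlation adjusted p = 0.291). Of 7 a-cell markers STE6, the a-factor exporter gene, rose at 7 min (0.78 ± 0.12) and 15-16 min (0.57 ± 0.12), and AGA2 (-0.80 ± 0.14), BAR1 (-0.51 ± 0.14) and MFA1 (-0.44 ± 0.12) fell at 60 min, as many as adjusted over the list alone (camera adjusted p = 0.0778), and of 4 alpha-cell markers 0 passed, also adjusted over the list alone.

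The Hsp90 list changed in both directions over time. Of its 23 genes 1 fell at 7 min, HSP104 (-1.21 ± 0.17), and 4 at 15-16 min, against 5 and 7 adjusted over the list alone. The camera adjusted p = 0.00406 and 0.0123, and with an estimated correlation adjusted p = 0.409 and adjusted p = 0.46. At 60 min 6 rose and 3 fell, the same counts as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.133). SIS1 (1.27 ± 0.19) rose and HSP26 (-1.89 ± 0.16), SSE2 (-1.05 ± 0.18) and HSP104 (-0.80 ± 0.17) fell.

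Averaged over all times, 12 of the 23 genes of the Hsp90 list were lower on the arrays labelled ppt1 than on the wild type arrays, 1 was higher and 10 did not pass (camera adjusted p = 8.35e-14; with an estimated correlation adjusted p = 0.122). SSA1 and SSA2, cytosolic Hsp70 genes, were lower by 2.13-fold and 2.1-fold, at -1.09 ± 0.12 (limma adjusted p = 0.00239) and -1.07 ± 0.11 (adjusted p = 0.0021). Of the Hsp90 co-chaperone genes, STI1 was at -0.95 ± 0.09 (adjusted p = 0.00127) and AHA1 at -0.77 ± 0.11 (adjusted p = 0.00881), and the Hsp90 gene HSC82 was at -0.78 ± 0.08 (adjusted p = 0.0021). Each of these 5 genes was lower in 5 of 5 matched pairs. The 5 times of a strain may come from 1 culture, so the pairs need not be independent. These directions rest on the labels, which PPT1 did not bear out. The values of SSA1 and SSA2, and of HSC82 and HSP82, are uncertain one against the other because near-identical genes share signal on an array, and so is that of YAL004W (-1.01 ± 0.13), which lies opposite SSA1.

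In total 221 genes passed, 101 higher and 120 lower on the arrays labelled ppt1, with a median difference of 0.464 in size. Median and MAD scaling gave 84 higher and 75 lower, quantile normalization 58 and 66, and the genes with a value on all 10 arrays gave 351 in total. Leaving out either array of a matched pair gave 56 genes at 0 min, 34 at 7 min, 96 at 15-16 min, 66 at 30 min and 77 at 60 min. The count was 0 with the time term left out. The lowest gene was PNC1, the nicotinamidase gene (-1.24 ± 0.10, adjusted p = 0.000587). After the genes above, SIS1 (-0.97), HSP104 (-0.88), CTR1, a copper transporter (-0.86), HSP12 (-0.80) and YDJ1, an Hsp40 gene (-0.74), were lowest. The highest were YDL038C (1.44 ± 0.10, adjusted p = 0.00049), the adjacent PRM7 (1.34 ± 0.16, adjusted p = 0.0042) and OLE1 (1.18 ± 0.17, adjusted p = 0.0092). They were followed by BSC1 (0.93), which neighbours YDL038C, FET4, a low-affinity iron transporter (0.91), IZH1, involved in zinc homeostasis (0.90), YOR338W (0.89), the hexose transporter gene HXT7 (0.86), YDR491C (0.83), which overlaps IZH1, SPG4 (0.78), TIP1, a cell wall mannoprotein gene (0.77), and YDL187C (0.75). YDL187C overlaps another gene, so its value, like those of YDL038C, BSC1 and YDR491C, is uncertain as to the transcript read. YOR338W lost its call under 10 of 19 alternatives, HXT7 under 9 of 18, BSC1 under 7 of 19, SPG4 under 5 of 18, YDL187C under 4 of 19, FET4 under 2 of 18 and YDJ1 under 2 of 19. PRM7 and YDL038C lost theirs under quantile normalization, at 0.60 and 0.55. Some of these alternatives, such as a natural log, could not change a call.

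Adjusted over the list alone, 17 genes of the Hsp90 list were lower on the arrays labelled ppt1 and 1 higher. The gene that was higher was HSP26 (0.45 ± 0.10), a small heat shock protein gene, and SSA4 (-0.02), FES1 (-0.07) and CDC37 (-0.13) were among those that did not pass. The list's median was -0.374, and it was below 0 in each matched pair, at -0.368, -0.493, -0.507, -0.369 and -0.438 in order of time. Of 31 proteasome genes 3 were lower, SCL1 (-0.47 ± 0.08), RPN12 (-0.44 ± 0.10) and PRE5 (-0.38 ± 0.08), and 8 adjusted over the list alone (camera adjusted p = 3.44e-05; with an estimated correlation adjusted p = 0.111). Of the general stress genes PNC1, HSP104, HSP12 and TPS1 were lower and HSP26 higher, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.0325; with an estimated correlation adjusted p = 0.439). Ribosome biogenesis (0 genes passed, 3 higher adjusted over the list alone) and the a-cell markers (1 gene higher, MFA1, 0.36 ± 0.08, and 2 adjusted over the list alone) were called higher by camera, with adjusted p = 0.00406 and 0.03, and with an estimated correlation adjusted p = 0.477 and adjusted p = 0.273. Sulfate genes (0 passed), G1/S genes (1 lower, CLB6, -0.60 ± 0.11) and TCA cycle genes (1 lower, CIT1, -0.52 ± 0.11) were called lower, with 6, 2 and 2 genes lower adjusted over the list alone and 1 sulfate gene higher, with adjusted p = 0.0108, 0.0122 and 0.0137, and with an estimated correlation adjusted p = 0.46, adjusted p = 0.325 and adjusted p = 0.46. The alpha-cell markers did not pass (adjusted p = 0.365), nor did the cell wall integrity list (adjusted p = 0.943).

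**Figure D3:**
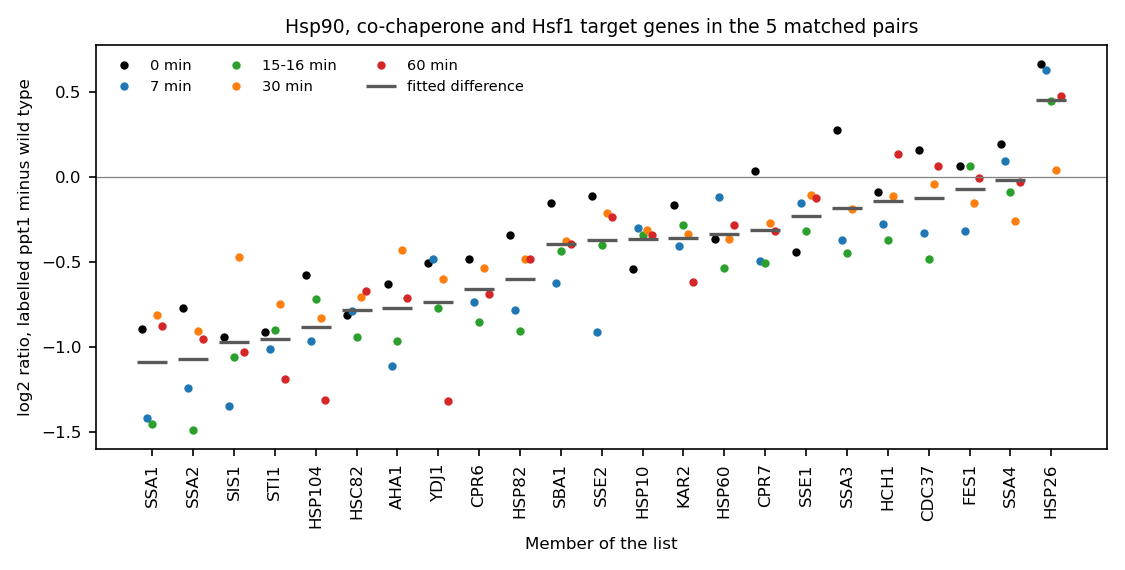
Difference in log2 ratio, labelled ppt1 minus wild type and likely sample over reference, for the 23 genes of the Hsp90 list, with 1 coloured point per matched time and a bar for the fitted difference. SSA1, SSA2, SIS1 and STI1 lie below 0 in 5 of 5 pairs and HSP26 lies above 0.

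No gene's strain difference passed the test for a change after the shift. In limma's interaction test 0 genes passed, and 273 had an unadjusted p under 0.05 where 290 would by chance. Each alternative that could be run also gave 0. Camera called 5 of the 25 lists, and 0 with an estimated correlation, where the lowest adjusted p = 0.156 was that of ribosome biogenesis. The genes with the highest moderated t, which did not pass (adjusted p = 0.993), were YLR345W (1.27 ± 0.21), PRM5 (1.20 ± 0.22), AZF1 (1.04 ± 0.23), TDA6 (0.97 ± 0.22) and YLR162W (1.31 ± 0.30). Those with the lowest were GND2 (-1.17 ± 0.23), NOP1 (-0.98 ± 0.23), GCV2 (-1.10 ± 0.26), DHR2 (-0.82 ± 0.20) and ESF2 (-0.96 ± 0.24). At this number of arrays, simulated 2-fold interactions were recovered in 22.1% of cases, so most changes of that size were not detectable.

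Each strain's own response, set against its own 0 min array, could be compared with the other's because the strains shared no array. Across genes the responses correlated at r = 0.531 at 7 min, 0.549 at 15-16 min, 0.731 at 30 min and 0.742 at 60 min. Among the genes measured in both strains (5628, 5394, 5489 and 5651 in order of time), 127, 204, 169 and 171 were at least 2-fold lower in the wild type and, on the arrays labelled ppt1, 65, 118, 197 and 218, with 45, 88, 109 and 127 in both. At least 2-fold higher were 6, 18, 24 and 27 genes in the wild type and 11, 26, 32 and 36 on the arrays labelled ppt1, with 3, 9, 14 and 14 in both. Over all genes measured in the strain itself, whether or not in the other, and summed over the 4 times, which strain had more 2-fold changes turned with scaling, from 766 in the wild type and 738 on the arrays labelled ppt1 to 438 and 542 with quantile normalization. These counts have no test, and they depend on the log base. At each time 0 genes changed 2-fold in opposite directions.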

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

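The tests on abundant transcripts, near-identical genes, general stress, PPT1 itself, the HOG list, the single 0 min arrays and the list median over 16 splits were chosen only after the result was seen. A total of 5 gene lists differed between the strains in their change after the shift by camera, and none of them did so with an estimated correlation. Each interaction sets the later pairs against the single pair at 0 min. A deviation of either 0 min array would therefore also appear as an interaction. The Hsp90 list had a median interaction of -0.248 (adjusted p = 0.0122; 0.455 with an estimated correlation). Ribosome biogenesis had -0.287 (adjusted p = 3.37e-06; 0.156 with an estimated correlation). Pheromone response had -0.268 (adjusted p = 0.00989; 0.432 with an estimated correlation). Sulfate assimilation had 0.337 (adjusted p = 0.00323; 0.409 with an estimated correlation). The TCA cycle list had 0.171 (adjusted p = 0.011; 0.414 with an estimated correlation).

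The 221 genes that differed between the strains were set against other splits of the 10 arrays, fitted with the time as a block. Of 100 splits 1, the labelled one, called as many genes, and the highest of the others called 2. Of these splits 22 part only 1 matched pair and 64 only 3, which leaves the strain difference in the residual, so that test is void. Only 16 splits part all 5 matched pairs, too few for a share under 0.05, and among them 1 called as many genes and the highest other called 0.

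The Hsp90 list was lower on the arrays labelled ppt1, with a median of -0.374. Of 100 splits 31 gave a list median as far from 0, the highest other being 0.507, but 30 of these part fewer than 5 pairs and so keep the strain difference of the pairs they part, which makes that test void, and in the 16 splits that part all pairs 1 did, with 0.329 as the highest other. A bias against abundant transcripts was argued against by ribosomal protein and glycolysis genes (median 0.0261, 95% interval 0.00405 to 0.0606). Dropping near-identical genes could not test shared signal, because the median stays below 0 whichever members are dropped in that number. The 15 members left had a median of -0.368 (interval -0.771 to -0.145), so the lower level was not confined to the near-identical genes. Both intervals are over genes and do not measure the spread between arrays. A general stress difference between the cultures cannot be told apart. It called for medians of the Msn2/Msn4 and ribosomal protein lists on opposite sides of 0, with both intervals excluding 0. Both intervals including 0 would have argued against it. Only the ribosomal protein interval excluded 0 (0.0439, from 0.0062 to 0.0657), and that of the Msn2/Msn4 list did not (-0.0797, from -0.33 to 0.039). The Msn2/Msn4 list shares HSP104, HSP26 and SSA4 with the Hsp90 list, and its other 21 members gave -0.0828 (from -0.33 to 0.039). Lower output of Hsf1 cannot be told apart either, because 9 further targets had a wide interval (-0.196, from -0.323 to 0.11). An effect of losing PPT1, or of any other difference between the 2 strains, stays open and untested.

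PPT1 was not lower on the arrays labelled ppt1, with a difference of 0.19 (95% interval -0.106 to 0.486). A spot that does not read the deleted part may account for this, and the lower bound of -0.106 leaves no room for a fall of 1 on the log2 scale, but spot intensities are not among the values used here, so it cannot be told apart from the rest. Exchanged strain labels or a turned ratio would make PPT1 higher, and the difference of 0.19 stays below 1. That argues against them only if the spot reads the deleted part, so they cannot be told apart either. A strain that still carries PPT1 was not tested.

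The cell wall integrity list fell after the shift to lower osmolarity, although cell wall stress by swelling is known to activate that pathway. A single deviating 0 min array was argued against by the weaker of the strains' own changes (-0.858, 95% interval -1.39 to -0.519, in the wild type). This interval too is over genes and not over arrays. A turned ratio cannot be told apart, because the HOG and glycerol list, with a median change of -0.843 at 60 min (from -1.42 to -0.672), is itself the basis on which the direction was taken as likely. Dropping members shared with other lists tested nothing, since only GSC2 is shared and the other 24 had a median of -0.979 (from -1.44 to -0.543). A high level of cell wall genes in the medium before the shift stays open as a biological explanation and was not tested.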

How the results depend on the processing

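Setting each time against the time before was chosen only after the result was seen, and the other alternatives were planned. Of the gene list results, 782 kept their direction and side of the threshold, 131 lost the call and 1 reversed. Of the named gene results, 1034 kept them, 41 lost the call and 0 reversed. These totals include alternatives that could not change a call, such as a natural log. They also hold the interaction genes, which had no call to lose. For the strain difference, leaving out either array of a pair gave the same fit, and both were counted. The causes of the changes below were not tested, except where fewer arrays or genes entered. Quantile normalization gave 53 genes at 7 min, 208 at 15-16 min, 437 at 30 min, 451 at 60 min, 124 for the strain difference and 438 wild type changes of 2-fold or more, against 176, 418, 661, 719, 221 and 766. Scaling to the median and MAD (median absolute deviation) gave 91 at 7 min, 255 at 15-16 min and 476 at 60 min. Genes with a value on all 10 arrays gave 351 for the strain difference, and array weights gave 274 at 15-16 min. Without the strain term 80, 209, 361 and 392 genes passed in order of time and 243 at any time, and without the time term 0 passed for the strain difference. After shock alone, with fewer arrays, 56 genes passed for the strain difference. Against the time before, 27 passed at 15-16 min, 3 at 30 min and 3 at 60 min. Camera with an estimated correlation passed 0 of 150 list tests, against 66. That setting also lowers the degrees of freedom, so the loss does not measure correlation between genes alone. With limma's fry 57 of the 150 passed, 1 of them for the interaction, but fry does not set a list against the other genes. Leaving out 1 array or time point gave 44 to 164 genes at 7 min, 162 to 392 at 15-16 min, 265 to 728 at 30 min, 273 to 780 at 60 min, 212 to 625 at any time and 34 to 96 for the strain difference. The lone array of a time was then assumed to vary like the others, and the interaction could not be fitted without either 0 min array. The ribosomal protein list at 15-16 min reversed without the wild type 16 min array (adjusted p = 0.794), and over the arrays left out its adjusted p lay between 4e-07 and that value. The filter on missing values and the treatment of each probe on its own removed nothing, so they tested nothing. Signal over background is not given in the sources used here, so its effect on precision is unknown.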

Other observations

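The tests of the purine, pyrimidine and zinc lists, and of steps between times, were chosen only after the result was seen, although the zinc genes had not been looked at when their test was set. Genes of purine and one-carbon synthesis fell after the shift, most of them by 15-16 min. Of 15 measured, 3 had fallen at 7 min, 11 at 15-16 min and 14 at 30 and at 60 min, with medians of -0.228, -1.4, -1.89 and -1.99. ADE17 (-4.18) and ADE2 (-3.10) had the lowest values at 60 min, and ADE16, which codes for the same activity as ADE17, stood at 0.19 and did not pass. In the step from 7 to 15-16 min 9 of the 15 fell (limma), with a median of -1.03. The list was drawn up because ADE17, ADE2 and SHM2 were among the largest falls, and it holds them, so its counts and medians describe the genes and give no test of the group.

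Of 7 pyrimidine synthesis genes 3 rose at 7 min, URA2 (0.67), URA4 (0.72) and URA1, whose rise was the largest of these, and 2 fell at 60 min, URA1 (-1.12) and URA4 (-0.50). This list too was drawn up after values were seen, so no test of the group's change over time is given.

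IZH1 and FET4, both linked to zinc by their regulation, were higher on the arrays labelled ppt1, so a wider change of zinc-regulated genes was tested as a hypothesis. The 10 measured members not yet looked at had a median strain difference of 0.201 (95% interval 0.0994 to 0.298), which goes with it. That interval is over genes and does not measure the spread between arrays. Camera gave the zinc list an adjusted p = 0.0106, and adjusted p = 0.15 with an estimated correlation, and 0 of the 10 passed alone. The pyrimidine list, to which no such hypothesis applied, had a median strain difference of 0.156 (camera adjusted p = 0.0169, and 0.15 with an estimated correlation). For the purine list it was 0.112 (camera adjusted p = 0.229). A shift of this kind was therefore not particular to the zinc list. The direction rests on labels that PPT1 did not bear out.

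The number of genes at least 2-fold from the reference was 312, 195, 181, 114 and 105 in the wild type in order of time, and 272, 123, 92, 114 and 80 on the arrays labelled ppt1. On the wild type 0 min array 2498 values had 4 decimals, all ending in 5, against 0 on the other arrays. Whether that array is a mean of repeated measurements is not given in the sources used here. Of 56 genes that differed between the strains after the shift alone, 53 differed in the same direction at 0 min. The median size over the 56 was 0.687 after the shift. At 0 min their median difference, counted as positive in that same direction, was 0.575. The 56 were chosen on the later arrays, which favours a larger value there, so these values do not show that the difference grew.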
